A study of Mus musculus with 16 samples.

How the data were processed

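Total RNA of homogenised mouse lungs was labelled with Cy3 and hybridised to Agilent 8 x 60K single-colour arrays, with 1 array per sample and 16 arrays on 2 slides. Per the file headers the images were read with Agilent Feature Extraction, version 10.10.1.1 in the submitters' processing notes, on a probe design placed on the mouse build mm9. The deposited file of each array holds intensity values in 1 channel, of which the background-subtracted and detrended signal was used, not scaled between arrays. The mean spot intensity, the local background intensity and the flags for brightness and outliers in the deposited files were used for filters and for 1 alternative. The authors' series table holds log2 values, and these matched the log2 signal minus the 75th percentile of each array. The authors' steps beyond these are not given in the sources used here.

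Groups were taken from the sample titles, which gave 4 ARF-DTR samples each at 2 months, at 12 months with PBS and at 12 months with DT, and 2 wild type samples each with PBS and with DT. For wild type PBS replicate 1 the free description names DT, and those of the wild type DT samples leave it out. The titles, source names and treatments were the same as each other and were used. Replicate numbers in the titles name samples, and the labels do not say that each came from a separate mouse, so p-values measure the spread between these samples, which may be technical.

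Each array carried 59305 spots with 55681 probes. Control spots and spots flagged as outliers (105 to 171 per array) were left out, spots of a probe were averaged, and 0 spots were saturated. Signals were log2-transformed and the 75th percentile of the array was subtracted. A probe was kept where it was well above background on at least 4 of the 16 arrays, whatever their group, which left 37043 probes. Gene names came from the RefSeq accession of a probe (27656 probes) or its symbol (3401), and otherwise from the file (24624). The brightest kept probe stood for each of the 7513 genes with several, giving 25678 genes. Kept probes of the same gene passed in both directions for 1 gene with age and 115 with DT.

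Changes were tested with limma 3.58.1 in R 4.3.3 (with jsonlite 2.0.0 and, at version 1.17.8, data.table), with 1 mean per group, all 16 arrays in 1 fit, moderated variances and two-sided tests, and a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Values given as ± beside a log2 change are standard errors of that fit. The contrasts were 12-month PBS against 2-month ARF-DTR, DT against PBS in ARF-DTR and in wild type, the interaction of the last 2, DT-treated 12-month against 2-month ARF-DTR, and ARF-DTR against wild type with PBS. These contrasts, the alternatives tried, the gene lists and the rule for naming genes were chosen before the data were examined. Comparisons of DT-treated ARF-DTR with both wild type groups of the same slide were added after seeing the data, once the slides were read from the file headers. Slide as a fixed term could not be fitted, since each group lay on a single slide.

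Genes to follow were chosen by rule: 4 study genes, per contrast up to 12 genes with the largest rise and 12 with the largest fall among those that passed, had non-overlapping groups and had a proper symbol, and up to 4 members of a described list. For the interaction the overlap was not asked for, and for genes moved back by DT the 10 with the largest smaller change were taken. Where a group had arrays near background, a fold is given as a lower bound. The bound sets the mean of the brighter group against the mean of the dimmer group after each of its values was raised to the lowest signal seen among probes well above background on that array, or kept at the probe's own value where that was higher. In all 45 lists of pathway genes and cell type markers were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, which tests whether genes of a set move on balance one way. The lists held 815 genes, of which 771 were measured in the lung above background and 40 were on more than 1 list.

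Because the age and DT contrasts share the PBS arrays with opposite sign, their relation was set beside 50 simulated data sets without effects and beside fits in which the 4 PBS arrays were split 2 and 2. The fit was tested on simulated data of 25678 genes in 3 data sets, with 200 genes changed in each. Of genes changed 1.5-fold, it recovered 58.8% for age, 60.8% for DT, 29% for DT in wild type, 12.3% for the interaction, 58.2% for DT-treated against 2-month and 40.2% for the genotypes. At 2-fold it recovered 80.5%, 78.5%, 64%, 54%, 81.2% and 72.7%. False calls made up 2.63% (interaction) to 8.29% (DT) of the calls at 1.5-fold, and 4.14% (interaction) to 6.24% (genotypes) at 2-fold. In 4 of these comparisons camera found 12 of 12 shifted lists and called 0 of 105 unshifted ones. Other splits of the real arrays, in which 0 to 3 genes passed, gave camera up to 22 lists with age and 23 with DT, so that its calls on these arrays are less certain than the simulation shows.

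The alternatives were quantile normalization, array medians, normexp background correction with an offset of 50, the authors' log2 values, other filters on dim probes, the mean of a gene's probes or every probe, fits on the compared arrays alone, a variance trend with robust moderation, array weights, replicate number as a block, other thresholds, other set tests, and leaving out each array. Annotation of exons and untranslated regions was not used here.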

Results

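Lung RNA was measured on 16 single-colour Agilent arrays, with 1 array per sample, from female mice in 5 groups. ARF-DTR mice carry a receptor for diphtheria toxin (DT) under the control of the Arf promoter. Arf is a product of the Cdkn2a locus that is expressed in senescent cells, so the toxin can kill the cells in which that promoter is active. There were 4 samples from ARF-DTR mice aged 2 months, which had no injection, and 4 each from ARF-DTR mice aged 12 months given saline (PBS) or DT. Another 4 samples came from wild type mice aged 12 months, 2 given PBS and 2 given DT, and served to show what DT does without the transgene. DT was injected into the peritoneum at 50 microgram per kg body weight at an interval of 2 weeks for 1 month.

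The 75th percentile of the probe signals, which sets the scale of each array, lay between 613 and 1088 intensity units, and between 55.6% and 66.9% of the probes were well above background on an array. The arrays filled 2 slides of 8. Slide 1 held both the 2-month and the 12-month PBS samples of ARF-DTR mice, and slide 2 held the DT-treated ARF-DTR samples and all 4 wild type samples. The 75th percentile was 980 ± 74.4 (SD, n = 8 arrays) on slide 1 and 665 ± 44.4 (SD, n = 8) on slide 2. The median absolute log2 difference between arrays was 0.15 within a group, 0.18 between groups of the same slide and 0.27 between slides. Comparisons of 12-month PBS with 2-month samples and of wild type DT with wild type PBS therefore lay within a slide. DT against PBS in ARF-DTR mice crossed slides, so that slide and DT cannot be told apart there. On slide 1 the 2-month arrays filled row 1 and the 12-month PBS arrays row 2, so that row and age cannot be told apart. On slide 2 the DT-treated ARF-DTR arrays filled row 1 and the wild type arrays row 2, so row and genotype went together. The number of arrays limits the precision, above all in the wild type groups.

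The first comparison addressed how the lung of ARF-DTR mice differs between 2 and 12 months. At 12 months, immunoglobulin and B cell genes were higher, the cell cycle inhibitor Cdkn1a rose, and collagen, vascular and smooth muscle genes were lower (4 arrays against 4). As lists these were called by camera at a preset correlation, and 0 were with an estimated correlation (adjusted p = 0.143 or more with an estimated correlation). The immunoglobulin light chain gene Igkv3-4 rose 64.2-fold (adjusted p = 0.000962) and Jchain, whose protein joins secreted IgA and IgM into polymers, by 4.87 ± 0.53 (log2, SE, adjusted p = 0.000256). PBS replicate 2 was lower than the other PBS arrays in both, and without it the log2 rise was 6.90 for Igkv3-4 and 5.46 for Jchain. Col1a1, a chain of type I collagen, fell by 1.08 ± 0.18 (adjusted p = 0.00421), and Dbp, an output gene of the circadian clock, fell by 2.86 ± 0.21 (adjusted p = 1.89e-05). Of 25678 genes tested, 1577 passed, 700 of them higher and 877 lower at 12 months. Of these, 330 were at least 2-fold higher and 81 at least 2-fold lower. The 12-month mice had been injected with PBS and the 2-month mice had not, so that age and injection went together.

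Another immunoglobulin gene, Igk-V21, rose by 5.51 ± 0.83, or by 6.65 without PBS replicate 2, and Igkv8-16 was at least 21.9-fold higher (adjusted p = 0.00162). The plasma cell genes Tnfrsf17, which encodes the survival receptor BCMA, and Mzb1, which encodes a chaperone of antibody assembly, rose at least 5.78-fold and by 2.10 ± 0.42. Of the 11 plasma cell and immunoglobulin genes measured 5 rose and 0 fell, and 6 rose and 0 fell when adjusted over the list alone. The set had a median change of 0.24 and a mean of 1.25 (camera adjusted p = 0.000616, adjusted p = 0.328 with an estimated correlation). Among 18 B cell markers 7 rose and 0 fell, and 15 and 0 when adjusted over the list alone, with a median change of 0.62 (camera adjusted p = 2.08e-11, adjusted p = 0.232 with an estimated correlation). They included the transcription factors Pou2af1 (1.23 ± 0.24) and Spib (0.79 ± 0.15). Cxcl13, a chemokine that draws B cells into follicles, rose by 2.31 ± 0.38. It was the 1 gene to rise over all genes among 13 of germinal centres and lymphoid tissue. When adjusted over the list alone 7 rose and 1 fell (median 0.57, camera adjusted p = 5.95e-05, adjusted p = 0.224 with an estimated correlation). Class II antigen presentation genes were higher by a median of 0.39, with 4 of 11 up over all genes, 8 when adjusted over the list alone and 0 down (camera adjusted p = 3.1e-07, adjusted p = 0.224 with an estimated correlation). Among them were Cd74, the class II invariant chain (0.41 ± 0.10), and H2-DMb1 (0.42 ± 0.09).

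Of 26 T cell markers 6 rose over all genes, with Cxcr3 up by 1.28 ± 0.19 and Cxcr6 by 1.13 ± 0.13. When adjusted over the list alone they were 7, with 1 that fell (median 0.28, camera adjusted p = 1.2e-05, adjusted p = 0.359 with an estimated correlation). Markers of natural killer and cytotoxic cells went the other way, 6 of 20 fell and 0 rose, 9 and 0 when adjusted over the list alone. The activating receptor genes Ncr1 (-1.05 ± 0.23) and Klra8 (-1.15 ± 0.28) were among them, and the median was -0.33 (camera adjusted p = 0.00098, adjusted p = 0.501 with an estimated correlation). Of 17 complement genes 3 rose, among them C4b by 0.71 ± 0.11 (5 when adjusted over the list alone, median 0.30, camera adjusted p = 0.000112, adjusted p = 0.369 with an estimated correlation). Of 8 mesothelial markers 5 rose, 6 when adjusted over the list alone, with Wt1 up by 1.81 ± 0.36 and Bnc1 up 2.84-fold (median 0.99, camera adjusted p = 1.36e-05, adjusted p = 0.239 with an estimated correlation). All 3 steroid sulfotransferase genes named here were among the largest rises, Sult2a1 at least 12.6-fold, Sult2a4 at least 5.66-fold and Sult2a6 at least 6.19-fold (adjusted p = 0.000121, 0.000128 and 0.000158). Other large rises were Speer4e (at least 12.6-fold, adjusted p = 0.00051), Cxcl5, a neutrophil chemokine (4.58 ± 0.60), Ubd, a ubiquitin-like modifier (at least 18.6-fold, adjusted p = 0.00329), and Oosp1 (at least 14.2-fold, adjusted p = 0.000188). The fitted log2 values depended on single arrays, from 5.28 to 6.39 for Ubd and 5.80 to 6.53 for Oosp1 without PBS replicate 2, to 4.69 for Ubd without PBS replicate 1, and from 4.79 to 5.48 for Speer4e without 2-month replicate 3. Ncr1 and Klra8 were among the genes no longer past the threshold without some single arrays, as were Cd74, H2-DMb1, Col3a1 and Pecam1.

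A part of the matrix and vessel genes fell. Of 20 fibrillar and basement membrane collagens 10 fell and 0 rose over all genes, 15 and 0 when adjusted over the list alone, with a median of -0.48 (camera adjusted p = 5.07e-10, adjusted p = 0.224 with an estimated correlation). Beside Col1a1 they included Col1a2 (-0.90 ± 0.14), Col3a1 (-1.13 ± 0.25) and Col4a1 (-0.62 ± 0.11). Of 16 smooth muscle and pericyte markers 6 fell, 10 when adjusted over the list alone, and 0 rose (median -0.50, camera adjusted p = 5.02e-09, adjusted p = 0.143 with an estimated correlation). Among them were the hedgehog-binding Hhip (-0.74 ± 0.10), the matrix protein gene Postn (-0.72 ± 0.12) and the growth factor receptor gene Pdgfrb (-0.66 ± 0.12). Of 23 vascular endothelial markers 7 fell, 12 when adjusted over the list alone, and 0 rose. Among these were the apelin receptor gene Aplnr (-1.73 ± 0.29), the endothelin receptor gene Ednrb (-0.63 ± 0.10) and Pecam1, which encodes CD31 (-0.27 ± 0.06). The endothelial median was -0.25 (camera adjusted p = 0.000144, adjusted p = 0.321 with an estimated correlation). Elastic fibre genes were lower at a median of -0.29, with 3 of 19 down over all genes, among them Mfap2 (-0.50 ± 0.09). When adjusted over the list alone, 9 elastic fibre genes were down and 1 up (camera adjusted p = 5.95e-05, adjusted p = 0.239 with an estimated correlation). The largest falls outside these lists included Veph1 (-2.20 ± 0.21), Prdm8 (-1.88 ± 0.25), Asxl3 (at least 2.58-fold, adjusted p = 0.00458), Mboat2 (-1.77 ± 0.11), Wfdc16 (-1.76 ± 0.17) and Gprc6a (-1.74 ± 0.18). Ccna1, Colec10 and Smco3 were at least 4.6-fold, 3.7-fold and 3.01-fold lower (adjusted p = 0.00064, 0.00149 and 0.00108).

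Clock genes moved in both directions. Of 17 measured 4 rose and 8 fell, 4 and 10 when adjusted over the list alone, with a median of -0.54 (camera adjusted p = 0.0103, adjusted p = 0.341 with an estimated correlation). Arntl, which encodes the activator BMAL1, rose by 1.77 ± 0.15 and the repressor Nfil3 by 1.30 ± 0.12, while Dbp and Nr1d1, which encodes REV-ERB alpha and represses Arntl, fell (Nr1d1 by 1.70 ± 0.17). The same 17 genes had the same sign between DT-treated ARF-DTR and DT-treated wild type mice, all aged 12 months and on slide 2. There Dbp was lower (-2.38, adjusted p = 0.00157) and Arntl higher (2.10, adjusted p = 0.000626) in ARF-DTR mice.

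**Figure D1:**
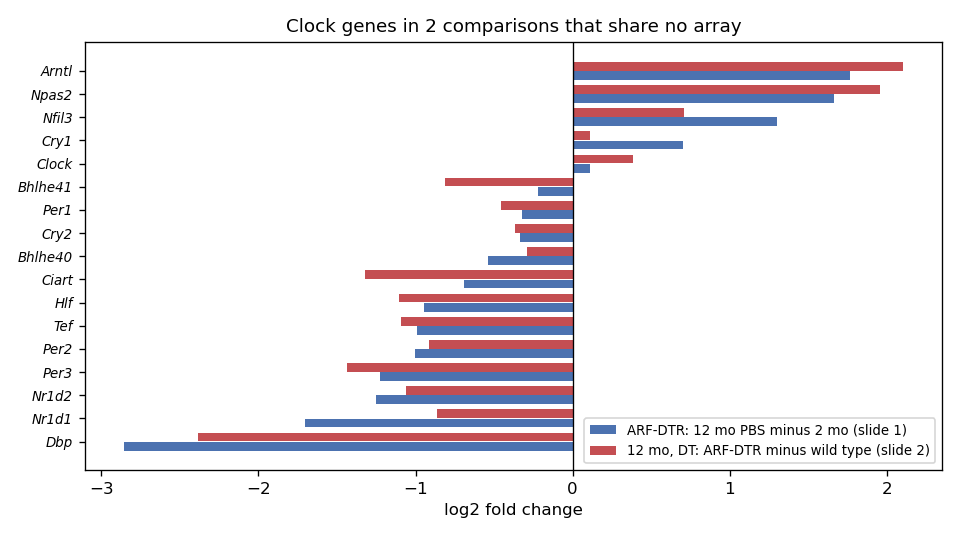
Log2 fold changes (x axis) of the 17 measured clock genes (y axis) between 12-month PBS and 2-month ARF-DTR lungs on slide 1 (blue, 4 arrays against 4) and between ARF-DTR and wild type lungs after DT at 12 months on slide 2 (red, 4 against 2). Both bars point the same way for all 17 genes, from Dbp at -2.86 and -2.38 to Arntl at 1.77 and 2.10.

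The series concerned genes linked to senescent cells, and 4 genes were followed whatever their values. Cdkn2a, the locus of Arf and p16, was at -0.34 ± 0.27 at 12 months and did not pass (adjusted p = 0.534). The probe used for it lay on chromosome 4 at 88920405 to 88920464 (mm9), and a second probe at 88920543 to 88920602 was well above background on 0 arrays. Its neighbour Cdkn2b (chromosome 4, 88952276 to 88952335) was at -0.13 ± 0.07 (adjusted p = 0.352). Cdkn1a, which encodes p21 (chromosome 17, 29237377 to 29237436), rose by 0.80 ± 0.11 (adjusted p = 0.00123). Hbegf, the mouse counterpart of the toxin receptor (chromosome 18, 36664738 to 36664797), was at -0.36 ± 0.13 (adjusted p = 0.113). Of the 18 cell cycle inhibitors and senescence regulators 2 rose, Cdkn1a and the stress cytokine gene Gdf15 (0.92 ± 0.17), and 1 fell (camera adjusted p = 0.637). Of 46 secreted factors of the senescence-associated secretory phenotype 7 rose, among them Cxcl5, Cxcl13 and Spp1, which encodes osteopontin (0.94 ± 0.16), and 2 fell. When adjusted over the list alone 9 rose and 3 fell (median 0.09, mean 0.35, camera adjusted p = 0.0268, adjusted p = 0.321 with an estimated correlation).

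Over the 45 lists camera called 23 with age, 14 higher and 9 lower. With an estimated correlation it called 0, the smallest adjusted p being 0.143, and 9 were at an unadjusted p under 0.05, while fry called 13. Of the 1577 genes 94.2% had every array of one group above every array of the other, as did 12.98% of all genes tested, where chance gives 2.86%. Without single arrays the count fell to 925 (2-month replicate 2), 933 (2-month replicate 1), 950 (PBS replicate 4), 1000 (2-month replicate 4) and 1014 (PBS replicate 3), and a fit on these 8 arrays alone gave 965. When arrays were scaled to their medians instead, 528 genes were higher and 1457 lower, on a shift of -0.12 in the median of all genes.

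The second comparison asked what DT changed in 12-month ARF-DTR lungs. Against PBS, ribosomal protein, alveolar type 2 cell, interferon and macrophage genes were higher in the DT-treated lungs and ciliated cell and smooth muscle genes were lower (4 arrays against 4), in a comparison that crossed slides. With an estimated correlation none of these lists was called (adjusted p = 0.844 or more with an estimated correlation). Sprr1a, a cornified envelope gene, was higher by 1.95 ± 0.19 (adjusted p = 3.64e-05) and Clec4n, which encodes the fungal receptor dectin-2, by 1.44 ± 0.15 (adjusted p = 5.17e-05). Ednrb was lower (-1.26 ± 0.10, adjusted p = 5.63e-06), as was Cox17, a copper chaperone for cytochrome oxidase (-2.85 ± 0.24, adjusted p = 1.36e-05). Against the wild type PBS arrays of the same slide, Sprr1a was still higher (1.68, adjusted p = 0.00349), as was Clec4n (1.04, adjusted p = 0.00958), and Ednrb was lower (-1.31, adjusted p = 0.000192). Cox17 was at -0.57 and did not pass (adjusted p = 0.286), and its second kept probe was at -0.19 against PBS. With DT in wild type lungs Sprr1a was at 0.76, Clec4n at 0.78 and Ednrb at -0.36, which did not pass (adjusted p = 0.249, 0.148 and 0.28).

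In all 7510 genes passed, 29.2% of those tested, 4058 higher and 3452 lower after DT, but 85 were at least 2-fold higher and 362 at least 2-fold lower. On the same slide, DT-treated ARF-DTR lungs differed from wild type PBS lungs in 1426 genes (549 higher, 877 lower) and from wild type DT lungs in 237 (156 higher, 81 lower). Of the 7510 genes, 556 also passed in the same direction against wild type PBS (208 higher, 348 lower) and 42 in the opposite one. Both comparisons used the same 4 DT arrays, as did the values on the slide given for genes and lists below. With these arrays split 2 and 2 between the comparisons, which leaves fewer arrays for each, a mean of 110.67 genes passed in the same direction and 14 in the opposite one over 6 splits. The correlation over genes between the comparisons was 0.43, where simulated groups without any effect that shared arrays gave 0.41. With the DT arrays split, so that no array was shared, it was 0.29 on average (0.28 to 0.31 over 6 splits). In the same direction against both wild type PBS and wild type DT 35 genes passed. Wild type PBS lungs, which had no DT, differed from PBS-treated ARF-DTR lungs with the same sign as DT did in 89.7% of the 7510 genes, and 3695 passed in that direction. With the PBS arrays split so that none served in both, 12.1% had opposite signs (8.98% to 17.02% over 6 splits). The median size of the change over the 7510 genes was 0.40 with DT and 0.06 in the same direction against wild type PBS on the slide.

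**Figure D2:**
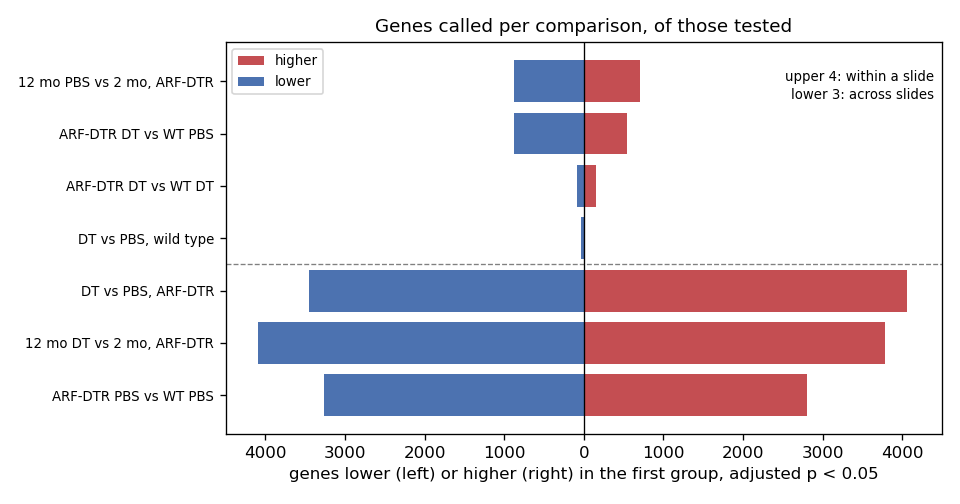
Number of genes (x axis) higher (red, right) or lower (blue, left) in the first group of each comparison (y axis) at an adjusted p under 0.05, of 25678 tested. The 4 comparisons within a slide gave 1577, 1426, 237 and 45 genes, and the 3 across slides gave 7510, 7879 and 6059.

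Among the largest rises, the arylacetamide deacetylase gene Aadac (at least 3.45-fold, adjusted p = 0.00156), Nnat (1.77 ± 0.23) and Mybpc2, a myosin-binding protein gene (1.63 ± 0.27), were also higher against wild type PBS on the slide (adjusted p = 0.0108, 0.023 and 0.0419, with 1.27 for Nnat and 1.28 for Mybpc2). DT in wild type lungs gave fitted values of 2.36, 0.44 and 0.88, which did not pass (adjusted p = 0.0586, 0.627 and 0.358). For Aadac no response of the transgene can be read from this. Isg15, an interferon-induced modifier (1.37 ± 0.25), Tnfrsf17 (1.37 ± 0.47), Slurp1 (1.34 ± 0.30) and Gpr55 (at least 1.98-fold, adjusted p = 0.0112) passed against PBS and not against wild type PBS (adjusted p = 0.278, 0.0864, 0.119 and 0.107). Of the largest falls, Lmntd1 (at least 3.9-fold lower) passed on the slide as well (adjusted p = 0.0404). The epithelial sodium channel gene Scnn1g (-1.90 ± 0.17), Cdh17 (at least 2.35-fold lower), the complement protease gene Masp1 (at least 2.51-fold) and Ube2d2b (at least 2.4-fold) did not. Scnn1g was at 0.10 there, and the others had arrays near background in both groups. A second kept probe of Masp1 had the opposite sign against PBS, at 0.53. Pet100, a cytochrome oxidase assembly gene, was at least 1.3-fold lower (adjusted p = 4.9e-05), but was at 0.14 under a different background correction. Another 8 genes were chosen after their values were seen, because they passed in the same direction in both comparisons. Higher in both were Ptx3, a soluble pattern receptor (1.24 against PBS, 1.98 against wild type PBS), Trem2, a lipid receptor of macrophages (1.23 and 1.36), and Il12b, the p40 subunit of IL-12 and IL-23 (1.02 and 1.46). In wild type lungs DT gave these 1.87, 1.497 and 1.503, which did not pass (adjusted p = 0.062, 0.159 and 0.164), so that no response of the transgene can be read from them. Those lower in both were Kif26b (-1.64 and -1.79), the lactate transporter gene Slc5a12 (-1.55 and -2.20), Tmeff2 (-1.29 and -1.65), Fibin (-1.20 and -1.42) and Wfdc16 (-1.18 and -1.52). In wild type lungs DT gave these, in the same order, -0.65, -0.78, -0.64, -0.37 and -0.34, which did not pass (adjusted p = 0.114, 0.133, 0.141, 0.424 and 0.6).

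Of 41 cytosolic ribosomal protein genes 40 rose and 0 fell against PBS, over all genes and when adjusted over the list alone. Among them were Rpl11 (0.54 ± 0.08) and Rps23 (0.50 ± 0.07), and the median was 0.39 (camera adjusted p = 1.38e-19, adjusted p = 0.844 with an estimated correlation). Against wild type PBS on the same slide their median was -0.05 (camera adjusted p = 0.205), with Rpl11 at -0.02 and Rps23 at -0.11. Of 35 oxidative phosphorylation genes 15 rose, 18 when adjusted over the list alone, and 0 fell (median 0.19, camera adjusted p = 0.000169, adjusted p = 0.846 with an estimated correlation), and their median on the slide was -0.04 (camera adjusted p = 0.248). Interferon response genes were higher by a median of 0.60, 14 of 31 over all genes and 23 when adjusted over the list alone, with 0 lower (camera adjusted p = 3.28e-07, adjusted p = 0.846 with an estimated correlation). On the slide their median was 0.16 (camera adjusted p = 0.0133, adjusted p = 0.767 with an estimated correlation), and Bst2, a tethering factor for viruses, was at 0.81 ± 0.14 against PBS and 0.14 there.

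Alveolar type 2 cell markers were higher in both settings, with medians of 0.61 and, on the slide, 0.37 (camera adjusted p = 5.64e-08 and 5.02e-06, adjusted p = 0.844 and 0.478 with an estimated correlation). Against PBS 15 of 16 rose, all 16 when adjusted over the list alone. They included the surfactant protein genes Sftpd (0.87 ± 0.10) and Sftpa1 (0.66 ± 0.10), Lyz2 (0.86 ± 0.13) and the surfactant-processing protease gene Napsa (0.82 ± 0.12). Of these Napsa passed on the slide (0.67, adjusted p = 0.0204). In wild type lungs DT gave it 0.60, which did not pass, so that no response of the transgene can be read from it. Ciliated cell markers were lower in both, with medians of -0.47 and -0.83 (camera adjusted p = 0.000169 and 1e-13, adjusted p = 0.846 and 0.478 with an estimated correlation). Against PBS 11 of 21 fell, 12 when adjusted over the list alone, among them Cdhr3 (-1.05 ± 0.19), the dynein gene Dnaic1 (-0.55 ± 0.14) and Hydin (-0.78 ± 0.16). Cdhr3 and Dnaic1 passed on the slide too (-0.94, adjusted p = 0.0332, and -0.87, adjusted p = 0.0162), where 11 of 21 were lower, 19 when adjusted over the list alone. In wild type lungs DT gave a median of -0.37 with 0 of 21 past the threshold (camera adjusted p = 0.00021, adjusted p = 0.685 with an estimated correlation), and the interaction was not called (median -0.09, camera adjusted p = 0.532).

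Macrophage and antigen-presenting cell genes were higher against PBS. Of 18 alveolar macrophage markers 10 rose and 0 fell, over all genes and when adjusted over the list alone, with Chil3 at 0.88 ± 0.21 and Ear1 at 0.76 ± 0.14. The median was 0.63 (camera adjusted p = 0.00823, adjusted p = 0.846 with an estimated correlation). Their median on the slide was 0.50 with 0 of 18 past the threshold, also when adjusted over the list alone (camera adjusted p = 0.000786, adjusted p = 0.478 with an estimated correlation), and -0.24 against wild type DT. Of 17 complement genes 9 rose, 10 when adjusted over the list alone, and 0 fell. C1qa (0.73 ± 0.15) and C1qb (0.79 ± 0.18), which encode subunits of C1q, also passed on the slide (0.85 and 0.88, adjusted p = 0.0227 and 0.0386). In wild type lungs DT gave these 0.67 and 0.72, which did not pass, so that no response of the transgene can be read from them. The set's medians were 0.60 and 0.44 (camera adjusted p = 0.000391 and 0.000119, adjusted p = 0.846 and 0.478 with an estimated correlation). Dendritic cell markers had medians of 0.45 and 0.33 (camera adjusted p = 0.00752 and 0.00052, adjusted p = 0.844 and 0.478 with an estimated correlation). Against PBS 8 of 14 were higher, also when adjusted over the list alone, among them Clec9a (0.60 ± 0.09) and the actin-bundling gene Fscn1 (0.77 ± 0.16). Class II genes were higher against PBS, 7 of 11 with 1 lower, and 7 with 2 lower when adjusted over the list alone (median 0.51, camera adjusted p = 0.00997, adjusted p = 0.846 with an estimated correlation). H2-Aa was at 0.94 ± 0.13 and Cd74 at 0.70 ± 0.10, and of these Cd74 passed on the slide (0.49, adjusted p = 0.0412). In wild type lungs DT gave Cd74 0.41, which did not pass, so that no response of the transgene can be read from it. On the slide the list was not called (median 0.25, mean 0.07, 1 of 11 higher and 0 lower, 3 and 2 when adjusted over the list alone, camera adjusted p = 0.194).

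Smooth muscle and pericyte markers were lower, 9 of 16 with 1 higher (10 and 1 when adjusted over the list alone), among them Acta2 (-0.71 ± 0.17) and the actin-binding gene Tagln (-0.58 ± 0.14). Their median was -0.38 against PBS and -0.21 on the slide (camera adjusted p = 0.00179 and 0.00276, adjusted p = 0.844 and 0.478 with an estimated correlation). On the slide 0 of 16 passed, also when adjusted over the list alone, and against wild type DT the median was 0.03. In wild type lungs DT gave -0.33, with 0 of 16 past the threshold (camera adjusted p = 0.000632, adjusted p = 0.266 with an estimated correlation). B cell markers were lower too, at medians of -0.32 and -0.67, with camera adjusted p = 0.0139 and 2.45e-06, and adjusted p = 0.851 and 0.478 with an estimated correlation. Against PBS 4 of 18 fell, over all genes and when adjusted over the list alone. Of 22 early stress response genes 10 fell and 2 rose, also when adjusted over the list alone. The mRNA decay factor gene Zfp36 was at -1.47 ± 0.15, the phosphatase gene Dusp1 at -0.78 ± 0.13 and Gadd45b at 0.45 ± 0.06 (median -0.33, camera adjusted p = 0.0387, adjusted p = 0.846 with an estimated correlation). On the slide this list was not called, with 3 higher and 3 lower, 5 and 8 when adjusted over the list alone (median -0.11, camera adjusted p = 0.261). Of 20 unfolded protein response genes 9 rose, 12 when adjusted over the list alone, and 0 fell, among them the chaperone genes Calr (0.37 ± 0.07) and Pdia3 (0.42 ± 0.07). The median of this set was 0.28 (camera adjusted p = 0.00122, adjusted p = 0.846 with an estimated correlation) and 0.09 on the slide, where it was not called (camera adjusted p = 0.205).

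Cdkn2a was at 0.34 ± 0.27 after DT and did not pass (adjusted p = 0.365), nor did Cdkn1a (0.18 ± 0.11, adjusted p = 0.234, its 3 kept probes at -0.44 to 0.85) or Hbegf (0.19 ± 0.13, adjusted p = 0.283). Cdkn2b fell by 0.29 ± 0.07 (adjusted p = 0.0116) against PBS and was at 0.14 against wild type PBS on the slide (adjusted p = 0.402). Camera called 17 lists, 12 higher and 5 lower, against PBS and 21 against wild type PBS. With an estimated correlation it called 0 of either, the smallest adjusted p being 0.844 and 0.478, with 0 and 3 lists at an unadjusted p under 0.05, while fry called 13 and 6. Of the 7510 genes 83.1% had groups that did not overlap, against 30.5% of all genes tested. Scaled to array medians 8695 genes were higher and 1759 lower, with the median of all genes shifted to 0.18, and a background correction by normexp gave 7198 and 2531. On the slide, scaling to array medians gave 899 and 505 genes against wild type PBS, and normexp gave 70 and 56 against wild type DT.

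**Figure D3:**
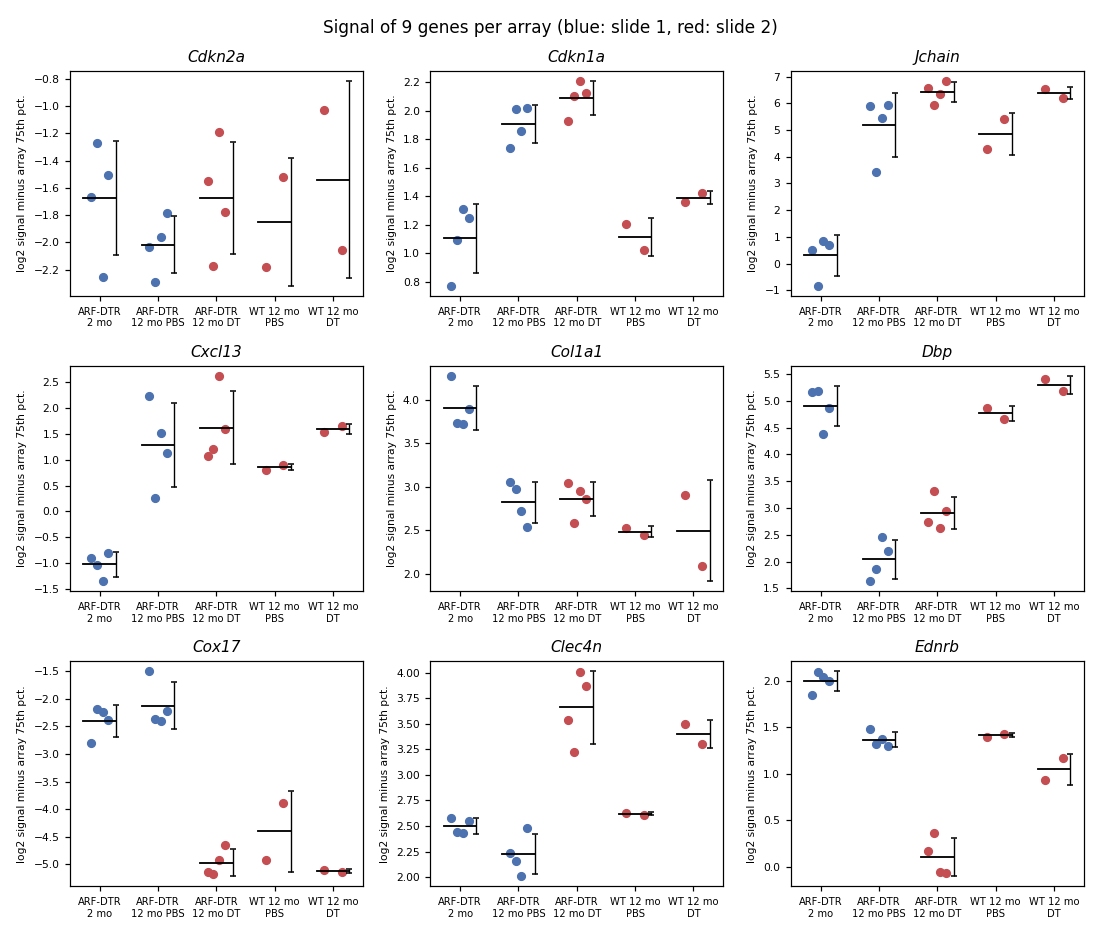
Log2 signal minus the 75th percentile of the array (y axis) of 9 genes in each of the 16 arrays, by group (x axis), with slide 1 in blue, slide 2 in red, lines for the group means and bars for the SD. Cdkn2a overlapped between the 2-month and 12-month PBS groups, Jchain and Cdkn1a were higher and Col1a1 and Dbp lower at 12 months with PBS, and Cox17 was lower on slide 2 in every group.

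DT was next compared with PBS in wild type lungs, on 1 slide with 2 arrays against 2, to show its effect without the transgene. Sgo2a, a protector of centromeric cohesion, was at least 3-fold higher (adjusted p = 0.0427). E2f7, a repressor of cell cycle genes, and Gas2l3, a cytokinesis gene, were higher by 1.04 ± 0.17 and 1.14 ± 0.18 (adjusted p = 0.0372 and 0.0316), with second kept probes at 0.07 and 0.46. Ch25h, which makes 25-hydroxycholesterol, rose by 1.04 ± 0.17, Plaur, the urokinase receptor gene, by 0.63 ± 0.10, and Glb1, the lysosomal beta-galactosidase gene, by 0.46 ± 0.08 (adjusted p = 0.0378, 0.0285 and 0.0427). Mapk8ip2, a scaffold of JNK signalling, was at least 5.64-fold lower (adjusted p = 0.00915), and Ccdc184 (-1.59 ± 0.20), Ccnjl (-1.40 ± 0.19) and the thyroxine transporter gene Slco1c1 (-0.74 ± 0.09) fell as well.

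In all 45 genes passed, 14 higher and 31 lower, and 3268 were at an unadjusted p under 0.05. Others that rose were Coq10b (0.87 ± 0.15), Plekhf1 (0.84 ± 0.14), Mark1 (0.70 ± 0.10) and Atp8b1 (0.69 ± 0.11), and among those that fell were Cst8 (-1.20 ± 0.18) and Rhox7a (-1.53 ± 0.27). Cdkn2a was at 0.31, Cdkn2b at -0.43 ± 0.10, Cdkn1a at 0.28 and Hbegf at -0.29, and none of these 4 passed (adjusted p = 0.812, 0.118, 0.502 and 0.544). Of 33 cell proliferation genes 0 passed over all genes and 9 rose when adjusted over the list alone, with a median of 0.66 (camera adjusted p = 5.45e-15, adjusted p = 0.369 with an estimated correlation). The spindle genes Prc1 and Tpx2 were at 0.92 and 0.85 (adjusted p = 0.132 and 0.149), with a second kept probe of Tpx2 at 0.02. Alveolar macrophage markers had a median of 0.59, with 0 passing over all genes and 2 when adjusted over the list alone (camera adjusted p = 1.56e-08, adjusted p = 0.159 with an estimated correlation). The macrophage elastase gene Mmp12 was at 2.04 (adjusted p = 0.15) and Itgax, which encodes CD11c, at 1.01 (adjusted p = 0.161). Of 22 p53 target genes 4 rose when adjusted over the list alone and 0 over all genes (median 0.11, camera adjusted p = 0.00517, adjusted p = 0.159 with an estimated correlation), and theirs was the 1 list that fry called (adjusted p = 0.00089). The cell proliferation list was not particular to wild type. Camera at the preset correlation also called it higher with DT against PBS in ARF-DTR lungs, across slides, and not with an estimated correlation. In DT-treated ARF-DTR against wild type DT lungs its median was -0.13.

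Camera called 19 lists in wild type, 12 higher and 7 lower, and with an estimated correlation 0, the smallest adjusted p being 0.159, with 7 at an unadjusted p under 0.05. Dendritic cell (0.34), complement (0.24), class II (0.25) and alveolar type 2 cell (0.17) lists were also higher, as in ARF-DTR lungs, with 0 genes past the threshold over all genes (camera adjusted p = 0.00154, 0.0171, 0.000641 and 0.00502, adjusted p = 0.266, 0.685, 0.505 and 0.685 with an estimated correlation). When adjusted over the list alone 4, 0, 3 and 1 rose, and the alveolar type 2 cell median was -0.0499 without wild type DT replicate 1. Lower lists included neutrophil (-0.997), platelet (-0.96), natural killer (-0.36) and mesothelial (-0.53) markers, with 0 genes past the threshold over all genes or over the list alone. Their camera adjusted p were 0.0148, 0.00996, 0.000334 and 0.0197 (adjusted p = 0.505, 0.701, 0.602 and 0.685 with an estimated correlation). The platelet median was 0.28 without wild type DT replicate 1. Without some single arrays Sgo2a, Gas2l3, E2f7, Ch25h, Plaur, Coq10b, Plekhf1, Mark1, Atp8b1, Rhox7a and Cst8 no longer passed, and the gene count depended on the arrays used. It was 78 and 87 without wild type PBS replicates 1 and 2, 126 and 233 without wild type DT replicates 1 and 2, 21 without DT-treated ARF-DTR replicate 4, and 0 when limma used these 4 arrays alone. Scaled to array medians 11 genes were higher and 15 lower, and after quantile normalization 17 and 23.

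Whether DT acted differently in the 2 genotypes was tested as an interaction term, which carried the difference between slides. Mapk8ip2 fell after DT in wild type and was at -0.10 ± 0.26 in ARF-DTR lungs, a difference that passed (adjusted p = 0.00772). As its wild type DT group lay near background, the difference was 2.39 with values raised to the lowest signal well above background. Plaur (-0.81 ± 0.12) and Igfbp7 (-1.16 ± 0.23) had a more negative response in ARF-DTR lungs (adjusted p = 0.0068 and 0.0253), although the 46 secreted factors did not as a list (median 0.05, 3 lower and 0 higher, 5 and 1 when adjusted over the list alone, camera adjusted p = 0.714). The transcription factor genes Klf4 (-1.10 ± 0.20) and Atf3 (-1.26 ± 0.25) did as well (adjusted p = 0.0193 and 0.0248). Zfp36 (-1.26 ± 0.26) and Ednrb (-0.90 ± 0.17) also differed in this direction, and Calr (0.56 ± 0.12) and Rps23 (0.53 ± 0.12) in the other. Without some single arrays Klf4, Atf3, Zfp36, Calr and Rps23 no longer passed. In all 541 genes passed, 219 with a more positive and 322 with a more negative response in ARF-DTR lungs.

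As a set, the 41 ribosomal protein genes had a more positive response (median 0.39, camera adjusted p = 6.37e-15, adjusted p = 0.892 with an estimated correlation), 1 over all genes and 35 when adjusted over the list alone. On slide 2, however, DT-treated ARF-DTR lungs had ribosomal medians of -0.05 against wild type PBS and -0.07 against wild type DT. The difference thus rests on the slide 1 PBS arrays and cannot be told apart from the slide. The 20 natural killer and cytotoxic cell markers also had a more positive response (median 0.80, camera adjusted p = 0.000446, adjusted p = 0.892 with an estimated correlation). Of these 0 passed over all genes, and 7 were higher and 1 lower when adjusted over the list alone. The 8 mesothelial markers did too (median 1.18, camera adjusted p = 0.000446, adjusted p = 0.892 with an estimated correlation), with 0 past the threshold over all genes and 7 higher when adjusted over the list alone. Both lists were lower with DT in wild type, by camera at the preset correlation and not at an estimated one. The early stress response genes had a more negative one, 3 lower and 1 higher over all genes and 8 and 2 when adjusted over the list alone (median -0.46, camera adjusted p = 0.00212, adjusted p = 0.892 with an estimated correlation). Camera called 11 lists, with an estimated correlation it called 0, with 0 at an unadjusted p under 0.05, and fry called 0. Scaling to array medians gave 335 genes with a more positive and 216 with a more negative response, and normexp 1643 and 390, with shifts of 0.14 and 0.12 in the median of all genes. The count was 227 and 274 without wild type PBS replicates 2 and 1, and 258 without wild type DT replicate 2. Without DT-treated ARF-DTR replicates 2, 3 and 4 it was 1110, 299 and 242, without PBS replicates 1 and 3 317 and 290, and without 2-month replicates 1 and 4 879 and 360.

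How far DT moved the age-changed genes back was addressed over the 1577 genes, bearing in mind that both contrasts use the PBS arrays with opposite sign. Speer4e rose with age at least 12.6-fold and fell with DT by 1.97 ± 0.58, and Cdhr1, a photoreceptor cadherin gene, rose at least 4.75-fold and fell at least 3.84-fold. Olig3 rose by 1.39 ± 0.29 and fell by 1.88 ± 0.29, and Cd177, a neutrophil surface gene, rose by 1.57 ± 0.20 and fell by 1.26 ± 0.20. Both were also lower against wild type PBS on the slide (-1.56 and -1.06, adjusted p = 0.0265 and 0.0298). Of the genes named in this paragraph, only Olig3, Cd177 and Veph1 passed there in the direction of DT. Veph1 fell with age and rose with DT by 0.99 ± 0.21, and by 0.999 against wild type PBS (adjusted p = 0.0422). Grip2 rose by 1.23 ± 0.30 and fell at least 2.72-fold. Lcn5 was at least 2.88-fold higher with age and at least 2.6-fold lower with DT, Ccna1 at least 4.6-fold lower and then at least 1.5-fold higher, and Colec10 at least 3.7-fold lower and then at least 1.06-fold higher (adjusted p with DT = 0.018, 0.0243 and 0.0252). The fitted log2 rise of Lcn5 with age went from 3.45 to 4.48 without PBS replicate 1 and to 2.73 without PBS replicate 4, where it did not pass (adjusted p = 0.118), and its fall with DT from -3.26 to -4.29 and -2.54. Without some single arrays Speer4e, Cdhr1, Ccna1 and Colec10 no longer passed with DT, nor Grip2 with age. Cyp3a57 and Dppa3, at least 1.4-fold and 1.66-fold higher with age (adjusted p = 0.00532 and 0.0251), passed as lower with DT but were at 0.07 and 0.000517 with the normexp background correction.

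Of the 1577 genes 360 passed with DT in the opposite direction, 142 that rose and then fell and 218 that fell and then rose, and 139 passed in the same direction. DT fold changes had the opposite sign in 57.2% of the 1577 genes. Simulated groups without any effect that shared the PBS arrays gave 88.0% for as many top genes. Those top genes were picked by noise in the shared arrays, so that 88.0% is not the value to expect of genes that truly differ. With the 4 PBS arrays split 2 and 2 between the contrasts, the share was 45.7% (37.0% to 52.7% over 6 splits) and the mean number moved back was 62.3, beside 79.3 moved further. Against wild type PBS on the same slide 97 genes were moved back, while 45 were higher and 71 lower in both comparisons, and the share of opposite signs was 40.0%. The correlation over genes between the age and DT fold changes was r = -0.07 (rho = -0.26), simulated groups gave -0.50, and the split arrays gave 0.04, with genes not being independent replicates. The number moved back was 745 with array medians, 636 with array weights and 175 in fits on the compared arrays alone. It was 182, 190 and 203 without 2-month replicates 1, 2 and 4, 184 and 191 without PBS replicates 3 and 4, and 224 without DT-treated replicate 4.

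DT-treated 12-month lungs were also compared with 2-month lungs of ARF-DTR mice, across slides. Immunoglobulin genes were higher, Igkv3-4 by 7.63 ± 0.81, Jchain by 6.12 ± 0.53 and Ighg by 5.52 ± 0.74 (adjusted p = 3.78e-05, 7.23e-06 and 0.000195). Wfdc16 (-2.94 ± 0.17), Slc5a12 (-2.48 ± 0.14) and the eye matrix gene Optc (-2.70 ± 0.38) were lower. Cdkn1a was higher by 0.98 ± 0.11 (adjusted p = 6.15e-05) and Cdkn2b lower (-0.42 ± 0.07, adjusted p = 0.00107), while Cdkn2a was at 0.00 (4 arrays against 4). In all 7879 genes passed, 3787 higher and 4092 lower, and 81.2% of them had groups that did not overlap. No comparison within a slide could be made for these groups, and scaling to array medians gave 4879 higher and 2558 lower genes and normexp 6566 and 3209. Of the 7879 genes 78.2% had the same sign between wild type PBS and PBS-treated ARF-DTR lungs, a comparison that shared no array with this one but crossed the same slides.

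Between the genotypes at 12 months with PBS, 4 arrays on slide 1 were set against 2 on slide 2, so that slide and genotype cannot be told apart. Spry4, a feedback inhibitor of receptor tyrosine kinases (2.19 ± 0.18), Tmem252 (2.20 ± 0.31) and Cox17 (2.28 ± 0.30, a second kept probe at 0.27) were higher in ARF-DTR lungs. Dbp (-2.72 ± 0.26), the retinoic acid hydroxylase gene Cyp26b1 (-2.95 ± 0.74), Ube2t (-2.01 ± 0.32) and Mapk8ip2 (-2.38 ± 0.32) were lower. Cdkn1a was higher by 0.79 ± 0.14 (adjusted p = 0.00222) and Cdkn2b by 0.43 ± 0.09 (adjusted p = 0.00582). On slide 2 alone Cdkn1a was higher in DT-treated ARF-DTR than in wild type PBS lungs by 0.98 (adjusted p = 0.00366), whereas Cox17 was not higher there. Of 41 ribosomal protein genes 39 were lower across the slides, 40 when adjusted over the list alone, and 0 higher (median -0.45, camera adjusted p = 3.76e-19, adjusted p = 0.889 with an estimated correlation). On slide 2 alone their median was -0.05 in DT-treated ARF-DTR against wild type PBS lungs. Quantile normalization gave 2667 higher and 2125 lower genes and a fold of at least 1.5 gave 1439 and 520, against the balance of the main fit. In the main fit 6059 genes passed in all, 2799 higher and 3260 lower. The count was 2323 and 2553 without wild type PBS replicates 1 and 2, and scaling to array medians gave 1938 and 4347 genes and normexp 1855 and 6071, each with a shift of -0.12.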

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

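The tests of DT as the whole cause of the DT-PBS difference, and both tests on the clock genes, were chosen only after the results they bear on were seen. The tests of the slide, of the column on the slide and of DT without the transgene, and the counts over other splits, were written down before.

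A single array lay apart from the other 3 of its group for 17 of the 310 groups examined over 143 genes, where chance gives about 1 in 20. Each value below is the gap to the nearest array divided by the range of the group. Among 2-month arrays these were Tnfrsf17 in replicate 2 (lowest, 0.8293), Oosp1 in replicate 1 (highest, 0.915), H2-DMb1 in replicate 3 (lowest, 0.924) and Dppa3 in replicate 1 (highest, 0.831). Among 12-month PBS arrays of ARF-DTR mice they were, in replicate 2, Tnfrsf17 (lowest, 0.888), Cyp3a57 (highest, 0.898) and Grip2 (highest, 0.832), in replicate 1 Spp1 (lowest, 0.861), in replicate 4 Masp1 (lowest, 0.886) and Acta2 (lowest, 0.844), and in replicate 3 Clec9a (lowest, 0.899), Pgbd5 (lowest, 0.849) and Dpysl4 (lowest, 0.833). Among DT-treated ARF-DTR arrays they were Nnat (lowest, 0.835), Masp1 (highest, 0.977) and H2-Aa (lowest, 0.943) in replicate 2, and Isg15 in replicate 3 (highest, 0.85).

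The response to DT differed between genotypes, by the interaction term, in 541 genes. Differences toward a more positive response in ARF-DTR lungs had the largest fitted values for Mapk8ip2 (2.91), Apoh (1.91), Mapk4 (1.73), Bean1 (1.68), Sez6 (1.57), Ccnjl (1.55), Adamtsl3 (1.40), Fcor (1.34), Snx22 (1.17), Hist2h3c2 (1.13), Tigd4 (1.12) and Krtap4-9 (1.12). Those toward a more negative one were Tas2r136 (-4.80), Pgbd5 (-2.73), Pet100 (-2.33), Krt24 (-2.19), Cd177 (-2.18), Osr2 (-2.18), Masp1 (-2.17), Cox17 (-2.13), Olfr1252 (-2.10), Adgrl2 (-1.94), Dpysl4 (-1.84) and Inha (-1.82). Several of these rest on groups near background, where the fitted size and order mean little. With values raised to the lowest signal well above background the differences were 2.39 for Mapk8ip2, 1.30 for Mapk4, 1.11 for Adamtsl3, 0.59 for Krtap4-9, -0.02 for Apoh and -0.20 for Sez6. They were -1.57 for Tas2r136, -1.47 for Pgbd5, -0.76 for Pet100, -1.16 for Krt24, -0.81 for Osr2 and -1.56 for Masp1, and Pet100 was at 0.38 with the normexp correction. Camera called 11 lists in the interaction, but 0 with an estimated correlation (adjusted p = 0.892 or more with an estimated correlation), and fry called 0. Their median differences were 0.60 for interferon response, 0.17 for oxidative phosphorylation (which turned direction with quantile normalization), 0.39 for ribosomal protein and 0.34 for unfolded protein response genes, and 0.47 for alveolar type 2 cell, 1.18 for mesothelial and 0.80 for natural killer and cytotoxic cell markers. They were -0.33 for cell proliferation and -0.46 for early stress response genes, -0.30 for T cell markers and -1.84 for cardiac and striated muscle genes. The ARF-DTR side of each of these differences crossed slides and the wild type side did not.

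The first pattern weighed is the large number of genes that differed between DT-treated and PBS-treated ARF-DTR lungs. DT as the whole cause is argued against by the same-slide wild type PBS arrays. With the DT arrays split so that none was shared, a mean of 55.68% of the genes kept their sign against them. Genotype and row on the slide differed there too. The slide may account for a part, since 78.21% of the genes called between DT-treated and 2-month lungs had the same sign between wild type PBS and PBS-treated ARF-DTR lungs, groups that share no array with the first. Genotype differed in the first of these tests, but cannot give the second, where DT-treated and 2-month mice had the same genotype. A part due to DT stays open. The 556 genes that also passed on the slide do not measure that part, since both comparisons used the same DT arrays. With these split a mean of 110.67 passed in the same direction, and 35 passed against both wild type groups with the arrays shared.

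The second pattern is the clock genes at 12 months with PBS against 2 months. Among mice of the same age 10 clock genes passed, between DT-treated ARF-DTR and DT-treated wild type lungs on slide 2. These differ in genotype, which keeps age open as the whole cause within ARF-DTR mice. A difference in the hour of collection is a candidate explanation, since all 17 of the measured clock genes had the same sign in that comparison and in the age comparison, as a shift along the daily cycle would give. DT against PBS in wild type lungs, of the same age and genotype on slide 2, gave Arntl at -1.17 and Ciart at 1.24 (2 arrays against 2). Per1 was at 1.08 there, with another kept probe at -0.16, and Per2 at 1.02. These genes had the smallest p of the list and did not pass over all genes. DT differed there, so that these values do not decide on age. The labels used here give no hour, and an effect of the transgene or of strain background on the clock was not tested.

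The third pattern is that fold changes with DT went the same way in ARF-DTR and in wild type lungs, with a correlation over genes of 0.2321 between contrasts that share no array. Such a relation may come from DT acting without the transgene, but whether it is specific to DT is open. The age contrast, which involves no DT and shares no array with the wild type contrast, correlated with it at 0.28875. By rank it hardly did (rho = 0.05), whereas the DT contrast had rho = 0.23. The 4 wild type arrays allow only 3 splits, too few for a share under 0.05, and the highest other split gave 0.2019. The wild type PBS and DT arrays lay in different columns of the slide. The same difference of columns in ARF-DTR groups correlated with the wild type contrast at 0.1741, between the bounds set for and against a column effect, so that column and DT cannot be told apart in wild type.

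Most counts were reached by few or none of the other splits of the arrays. The splits cannot exclude chance differences between mice, since the samples may not come from separate mice, nor a cause that follows the slide. The real split was the 1 of 35 with as many genes for age (1577, highest other 0), for DT in ARF-DTR (7510, highest other 3) and for DT-treated against 2-month lungs (7879, highest other 11), though the last 2 real splits also follow the slide. It was the 1 of 35 for lists with age (23, highest other 22), a margin of 1 list that is smaller than the range of 20 to 25 lists without single arrays. For lists with DT in ARF-DTR 11 of 35 splits gave as many as the real 17, the highest other 23, so that count lay within the range of other splits. For genes moved back by DT 3 of 100 drawn splits gave as many as the real 360. The highest other, 4406, kept the 4 DT arrays together as the middle group against mixed slide 1 arrays and so follows the slide, a structure of the samples several times the real count, and the next, 1068, exchanged the 2-month and PBS groups. With the wild type PBS arrays as the control of DT, which lie on its slide, 97 were moved back, fewer than those that passed in the same direction (45 higher and 71 lower in both).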

How the results depend on the processing

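The comparisons with wild type arrays on the same slide were added after seeing the data, and the others were chosen earlier. Over those, each gene in each contrast was counted once per setting. The genes were those chosen by rule and some that passed against both PBS and wild type PBS. The count held genes that did not pass in the main fit, and fits without an array from outside the contrast. The side of the threshold, and the direction of genes past it, was kept in 11385 cases. In 839 cases the gene was no longer past it, in 74 it passed newly and in 8 it reversed. Lists did so in 1890, 207, 0 and 3 cases. Counts stayed within 1.5-fold, and shares within a binomial interval over the age-changed genes, in 299 cases, moved further in 69 and reversed in 4. That interval takes genes as independent, which they are not, so that it does not measure the spread between samples. Except where fewer arrays or a different threshold make the count, the cause was not tested. Signal over background limits the dim genes, and each gene that reversed with another background correction had a group near background.

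With normexp, genes with DT in wild type numbered 20 and interaction genes 2033, and the share of age-changed genes with an opposite DT change was 60.95%. Reversed values were Pet100 with DT (0.14) and in the interaction (0.38), Dppa3 (0.000517) and Cyp3a57 (0.0714) with DT, Chrm1 between DT-treated and 2-month lungs (0.0879), and Sele (-0.0460), Bahcc1 (-0.0192) and Olfr401 (-0.0420) between genotypes. Quantile normalization gave 7 interaction lists and a median of 0.0126 for oxidative phosphorylation genes in the interaction, where the set test turned its direction (adjusted p = 0.83). Scaling to array medians gave 26 genes with DT in wild type, 745 moved back and a share of 70.6%. Without a filter on dim probes 289 interaction genes passed, probes above background on all 16 arrays gave 26 genes with DT in wild type, and testing every probe gave 74.

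Fits on the compared arrays alone gave 965 genes with age, 0 with DT in wild type, 175 moved back and a share of 50.5%. A variance trend with robust moderation gave 813 interaction genes, and array weights gave 15 genes with DT in wild type and 636 moved back. A fold of at least 1.5 left 781 genes with age, 1798 with DT, 2466 between DT-treated and 2-month lungs, 1959 between genotypes and 88 moved back, with a share of 48.9%. An adjusted p under 0.1 gave 2543 genes with age, 172 with DT in wild type, 1651 in the interaction and 761 moved back, with a share of 60.3%. Camera with an estimated correlation called 0 lists for age, DT, DT in wild type and the interaction, with 9, 0, 7 and 0 at an unadjusted p under 0.05, and fry called 13 for age, 13 for DT, 1 for DT in wild type and 0 for the interaction.

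With the PBS arrays split the share was 45.7% and 62.3 genes moved back. With wild type PBS in the age contrast the share was 20.7%. That age contrast and the DT contrast crossed the slides in the same direction, so that a slide difference by itself would lower this share. The value of 20.7% therefore does not measure how far DT moved genes back. Against wild type PBS on the same slide 1426 genes passed, 97 moved back and the share was 40.0%. Of the 115 genes followed for DT, some were chosen because they passed in both comparisons, so that their calls could not change here. With these included 39 kept their call, which is thus no measure of agreement. Another 63 no longer passed, 1 passed newly and 12 reversed: Myh8 (0.12), Scnn1g (0.10), Cdkn2b (0.14), Tyms (0.11), Gadd45b (-0.0271), Ndufb3 (-0.10), Ndufa2 (-0.11), Rpl14 (-0.0591), Rps23 (-0.11), Rpl11 (-0.0166), Pdia6 (-0.0413) and Higd1b (-0.16). The medians of oxidative phosphorylation (-0.0382) and ribosomal protein genes (-0.0458) reversed too. Against wild type DT 237 genes passed, and the medians that reversed were cell proliferation (-0.13), class II (-0.0594), oxidative phosphorylation (-0.0536) and ribosomal protein genes (-0.0732), and smooth muscle (0.0264), alveolar macrophage (-0.24) and monocyte (-0.0882) markers.

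Leaving out single arrays gave 925 to 1786 genes with age, 5383 to 8200 with DT, 21 to 233 with DT in wild type, 227 to 1110 in the interaction, 6046 to 8367 between DT-treated and 2-month lungs, 2323 to 6715 between genotypes and 182 to 448 moved back, with shares of 49.8% to 61.4%. Lists numbered 20 to 25, 14 to 18, 16 to 25 and 10 to 14 for age, DT, DT in wild type and the interaction. The share fell to 49.8% without 2-month replicate 1. Without wild type DT replicate 1 the medians of alveolar type 2 cell (-0.0499) and platelet markers (0.28) with DT in wild type reversed, and without replicate 2 they were 0.514 and -2.21. Where this left 1 array in a wild type group, the lone sample is assumed to vary like the other groups.

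With replicate number as a block the counts were 1486 genes with age, 7428 with DT, 65 with DT in wild type, 516 in the interaction, 7887 between DT-treated and 2-month lungs, 5647 between genotypes and 337 moved back. The numbers do not pair the arrays, since residuals of PBS and DT arrays of the same number correlated over genes at 0.10, 0.33, -0.06 and 0.05. Slide as a fixed block could not be fitted, slide as a random block was not run because the correlation estimated within slides, with each group on 1 slide, was 0 and leaves the fit as it is, and scan date was not run because it is the same as the slide.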

Other observations

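On slide 2 alone, in the comparison added after seeing the data, DT-treated ARF-DTR lungs differed from wild type PBS lungs in further gene groups (4 arrays against 2). Collagen genes, which were lower at 12 months than at 2 months in ARF-DTR mice, were higher than in wild type here. Of 20 genes 5 were higher and 0 lower, 6 and 0 when adjusted over the list alone. Among them was the basement membrane collagen gene Col4a1 at 0.57 ± 0.13 (median of the set 0.35, camera adjusted p = 0.000119, adjusted p = 0.478 with an estimated correlation). Of 22 p53 target genes 5 were higher, among them Cdkn1a at 0.98 ± 0.14, and 2 lower, 7 and 3 when adjusted over the list alone (median 0.11, camera adjusted p = 0.0265, adjusted p = 0.478 with an estimated correlation). Of 29 genes of xenobiotic and glutathione metabolism 4 were lower and 0 higher, 12 and 0 when adjusted over the list alone (median -0.32, camera adjusted p = 8.49e-07, adjusted p = 0.478 with an estimated correlation). Club and secretory airway cell markers had a median of -0.66, with 0 of 13 past the threshold over all genes or over the list alone (camera adjusted p = 0.0161, adjusted p = 0.767 with an estimated correlation). With DT against PBS in ARF-DTR mice the medians of the p53 target genes (0.11) and club cell markers (-0.61) were close to these, although camera called neither (adjusted p = 0.45 and 0.761) and fry called the p53 target genes (adjusted p = 0.00166). Cdkn1a was also higher than in DT-treated wild type lungs (0.70 ± 0.14, adjusted p = 0.0376), as was Cdkn2b (0.57 ± 0.09, adjusted p = 0.0153).

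With age, further lists moved that the account above left out. Of 21 fibroblast markers, 7 of which stand on other lists as well, 5 fell, 9 fell and 1 rose when adjusted over the list alone (median -0.25, camera adjusted p = 5.95e-05, adjusted p = 0.216 with an estimated correlation). Of 18 monocyte and interstitial macrophage markers 3 rose, 6 when adjusted over the list alone (median 0.24, camera adjusted p = 0.0001, adjusted p = 0.224 with an estimated correlation). Ciliated cell markers had a median of 0.37 with age, although 0 of 21 passed (camera adjusted p = 9.52e-06, adjusted p = 0.465 with an estimated correlation). Of 6 thyroid and parathyroid genes, markers of a tissue that lies near the airway, 3 rose with age, also when adjusted over the list alone (median 0.46, camera adjusted p = 0.00475, adjusted p = 0.19 with an estimated correlation). Cardiac and striated muscle genes were lower with DT in ARF-DTR lungs, at a median of -1.21, where 2 of 20 fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 0.0207, adjusted p = 0.861 with an estimated correlation). That comparison crossed slides, and against wild type PBS on the same slide their median was 0.05 with 0 of 20 past the threshold (camera adjusted p = 0.998). Xenobiotic and glutathione metabolism (3 of 29 rose, 4 when adjusted over the list alone), unfolded protein response (3 of 20, also over the list alone) and neutrophil (2 of 18, also over the list alone) lists were higher with age, with medians of 0.11, 0.09 and 0.35 and 0 genes lower. Camera gave adjusted p = 0.00307, 0.00904 and 0.00803 (adjusted p = 0.501, 0.588 and 0.348 with an estimated correlation). Interferon response genes (median -0.20, 0 of 31 past the threshold) and alveolar type 1 cell markers (median -0.12, 1 up and 1 down of 14, 1 and 3 when adjusted over the list alone) were lower. For these camera gave adjusted p = 0.0336 and 0.0288 (adjusted p = 0.864 and 0.465 with an estimated correlation).

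Over all arrays the first principal component held 36.5% of the variance and the second 14.3%. On the first the 2-month arrays lay between -63.2 and -52.3, the 12-month PBS arrays of ARF-DTR mice between -27.3 and 5.63, and all arrays of slide 2 between 8.18 and 44.1.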
